A study of Mus musculus with 24 samples.

How the data were processed

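The series measured polyadenylated RNA by bulk sequencing in lung macrophages sorted from wild-type C57BL/6J mice and from knock-in mice that carry EGFP as a reporter of Spp1. Mice had received bleomycin (3 µg per g body weight), a drug that injures the lung and is used to model fibrosis, or PBS, into the trachea. Lungs were taken at day 7, 14 or 30. The gates were CD11b+ SiglecF- cells, called interstitial macrophages (IMs) here, and CD11b- SiglecF+ cells, called alveolar macrophages (AMs) here. Reporter cells were also sorted by EGFP. The 24 libraries form 8 groups of 3.

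Per the submitters' processing notes, reads were checked with FastQC 0.11.5, trimmed with Trimmomatic 0.38, aligned to GRCm38 with HISAT2 2.1.0 and counted per gene with featureCounts 1.6.3. SAMtools is named without a version, and neither the annotation release nor the strand setting is stated. The authors deposited raw read counts per gene in 2 tables. Every value was a whole number of 0 or more, with no scaling or filter visible. One table holds 49585 genes and 15 libraries: the wild-type IMs, both day 7 reporter IM groups and the PBS AMs. The other holds 55487 genes and 9 libraries: the day 14 IMs, the day 14 AMs and the day 30 AMs. Another 3 columns of counts match no sample and were not used. Rows were joined by Ensembl gene ID, of which 49022 occur in both tables and hold at least 99.486% of the counts of each library. Of the shared genes, 90.8% have the same chromosome name, strand, start and end in both tables. A share of 85.3% (41803 genes) also have no overlapping gene whose coordinates differ. The latter are called unchanged models here. Of the IDs, 99.478% of one table and 99.376% of the other occur in GENCODE M21, which was used only for this check. Gene symbols and positions are those of the deposited tables, on GRCm38.

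Total counts ran from 13450053 to 24580620 per library. Levels are in CPM, the usual scaling of counts to the total of the library. Group values in the text are means ± SD of CPM scaled by the factors of the fit, with n = 3 libraries per group unless stated. Values quoted across all 8 groups, and those in plots, are CPM of the total count. Floors from counts cover counting error only, and the reads carry no molecular identifiers. The SE of a log2 fold change was derived from its F test, as the absolute change over the square root of F. It therefore includes the spread between libraries. A fold against a group with a count of 0 is given as a lower bound, against a floor of 3 counts over the whole group. Where a group had 1 to 3 counts, levels are given in place of a fold.

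Genes were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, filterByExpr and the robust quasi-likelihood F test, 2-sided, with group as the single term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. Every adjusted p for a gene is from this test. The wild-type IMs, the 9 reporter IM libraries, the 9 AM libraries and the 6 EGFP+ day 14 libraries were fitted separately. Comparisons between IMs at day 14 and day 7, and between AMs after bleomycin and after PBS, span both tables, so that table and group cannot be told apart there. Comparisons within one table are those of the wild-type IMs, of EGFP+ with EGFP- IMs, of day 30 with day 14 AMs, and of IMs with AMs at day 14.

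The gene lists, comparisons, tests and naming rule were fixed before the data were examined. There are 17 pathway lists and 13 lists of markers of other cell types, RNA quality or sex. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at an inter-gene correlation of 0.01. The p was adjusted within a comparison over the pathway lists, or over the 13 others. The same test was run with an estimated correlation, and fry was run beside it. Counts of called members are over all genes tested. The counts adjusted over the list alone are given where they differ, and are otherwise equal to these. The naming rule took Spp1, Siglecf and Itgam. It then took the 10 called genes with the largest change each way among those with at least 10 CPM in the higher group and no overlap between replicates, leaving out predicted genes and pseudogenes. From each list it took the 4 members with the smallest p. Where tables differ, the same rule was also applied to autosomal genes with unchanged models, a choice made after the values were seen.

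Overlaps between comparisons were counted against the product of the 2 call counts over the genes tested in both. For the pair that shares the PBS AM libraries, the covariance of log2 fold changes was set beside the mean of 10 simulations without an effect. Principal components used the 2000 most variable genes. The edgeR test was tested on simulated data with 200 changed genes, 67 at 1.5-fold, 67 at 2-fold and 66 at 4-fold. Of those at 1.5-fold it recovered 83.6% in the wild-type IM comparison and 52.2% in the EGFP+ against EGFP- comparison. It recovered 76.1% in the AM day 14 comparison and 16.4% in the day 14 IM against AM comparison. At 2-fold the recovery was 100%, 86.6%, 100% and 80.6%, and at 4-fold it was 100% in all 4. False calls made up 7.07% to 9.66% of the calls, above the nominal level.

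Alternatives were DESeq2 1.42.0, its size factors in place of TMM, no low-count filter, a stricter one (5 CPM in at least 3 libraries), all libraries in one fit, only the 2 groups compared, replicate number as a block, a minimum log2 fold change of 1, and each library left out in turn. Autosomal genes with the same coordinates, or with unchanged models, were 2 further alternatives, both added after the data were seen. The labels do not say whether libraries with the same number came from the same mice. Residuals paired clearly by number only between IMs and AMs at day 14 (r of 0.148 to 0.246 across genes). The reported values use no block, so in that comparison they leave the pairing out. Its gene counts and Spp1 are also given with a block. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. Immunoglobulin segments, Hspa1a with Hspa1b, MHC class II genes, the Ear genes and haemoglobin genes have close copies or overlaps, so their counts may be shared among copies. Sequence reads were not analysed here.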

Results

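Bulk RNA sequencing counted transcripts in 24 libraries of sorted mouse lung macrophages, in 8 groups of 3. The wild-type interstitial macrophages (IMs) were taken at day 7 after PBS or bleomycin. The reporter mice gave EGFP- and EGFP+ IMs at day 7 after bleomycin, EGFP+ IMs at day 14 after bleomycin, and EGFP+ alveolar macrophages (AMs) at day 7 after PBS and at days 14 and 30 after bleomycin. The PBS AM libraries held 18227184 to 24580620 counts each, and the other libraries 13450053 to 17848593. The 10 most abundant genes of a library took 5.50% to 15% of its counts. In a principal component analysis of all libraries, the PC1 axis carried 50.3% of the variance and PC2 23.4%.

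Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) encodes osteopontin, a secreted matrix protein, and is the gene that EGFP reports. Its level was 91.3 ± 2.78 CPM in wild-type IMs after PBS and 3437 ± 271 CPM after bleomycin. In reporter IMs at day 7 it was 518 ± 59.5 CPM in the EGFP- gate and 4103 ± 597 CPM in the EGFP+ gate, and in EGFP+ IMs at day 14 it was 5898 ± 1660 CPM. EGFP+ AMs held 202 ± 9.47 CPM after PBS, 4808 ± 1421 CPM at day 14 and 6822 ± 136 CPM at day 30. The sort genes followed the gates. Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531), which encodes SiglecF, had group means of 7.42 to 25.1 CPM in IMs and 122.5 to 415 CPM in AMs. Itgam (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491), which encodes CD11b, had group means of 218 to 379 CPM in IMs and 7.32 to 26.1 CPM in AMs.

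**Figure D1:**
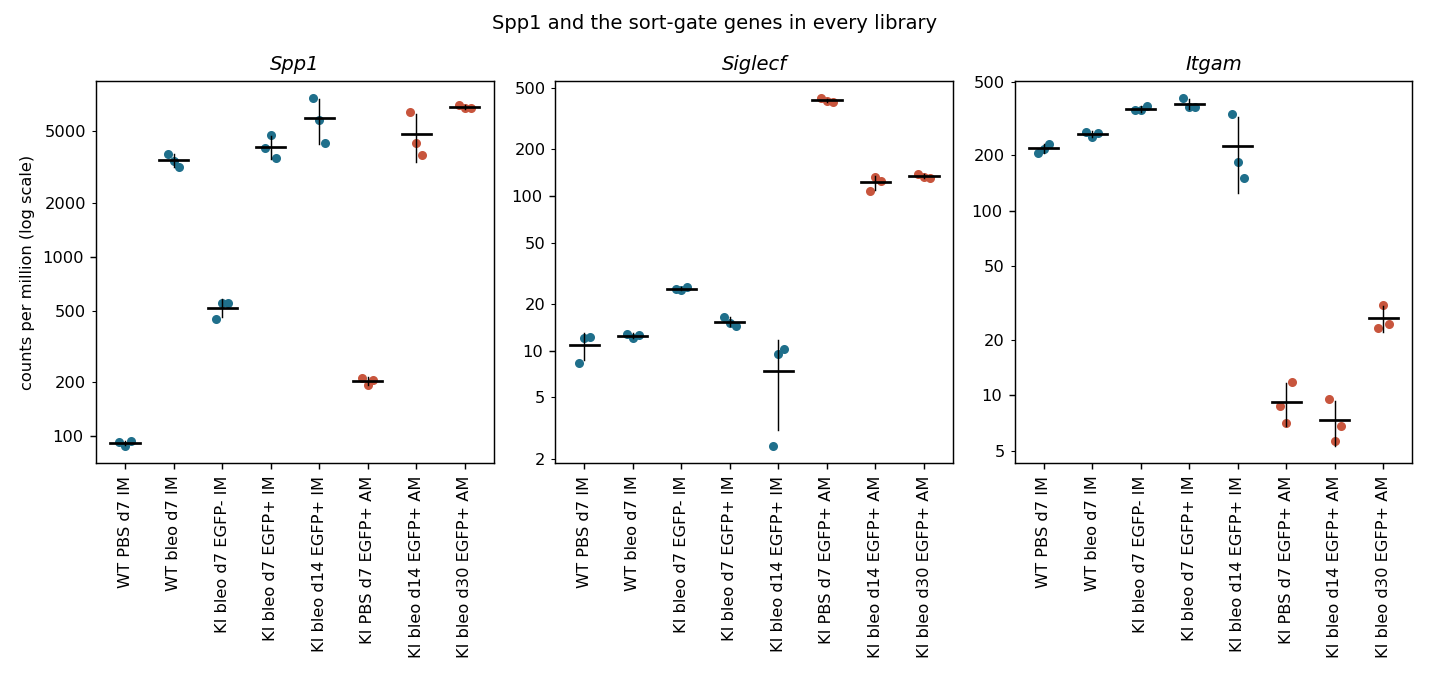
CPM of the total count on a log axis for Spp1, Siglecf and Itgam in each of the 24 libraries (points), with the group mean (horizontal bar) and SD (vertical line) of 3 libraries; blue is the IM gate and red the AM gate. Spp1 is lowest in the PBS groups, at 91.3 CPM in wild-type IMs and 202 CPM in AMs, while Siglecf and Itgam separate the gates.

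The comparison of wild-type IMs at day 7 asks what bleomycin changed in this gate. Spp1 was 36.5-fold higher after bleomycin (log2 fold change 5.19 ± 0.07 SE, adjusted p = 3.0e-23, 3 against 3 libraries). Arg1, which encodes an arginine-degrading enzyme of repair-type macrophages, rose 268-fold, from 1.81 ± 0.65 to 487 ± 52.1 CPM. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, rose 94.3-fold to 1024 ± 57.3 CPM. F7, coagulation factor VII, rose from 5.17 ± 1.79 to 129 ± 4.28 CPM and Pdpn, which encodes podoplanin, rose 18.0-fold. Fn1, which encodes fibronectin, rose from 594 ± 65.0 to 4929 ± 250 CPM, whereas the lipid receptor gene Cd36 fell from 519.8 ± 15.3 to 189 ± 3.90 CPM. Itgam was 1.16-fold higher (adjusted p = 0.00121), a difference that was not past the test with all libraries in one fit, and Siglecf did not differ by the test (adjusted p = 0.333).

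All 20 lipid-associated macrophage genes of the Trem2 and Gpnmb type rose (adjusted p = 4.0e-09 by camera, adjusted p = 0.233 with an estimated correlation). Among them, the lysosomal protease gene Ctsd rose 6.90-fold and the lipase gene Lpl 6.88-fold, to 1012 ± 27.4 CPM. All 29 cell cycle genes rose (adjusted p = 8.1e-11, adjusted p = 0.233 with an estimated correlation). Ccna2, cyclin A, rose 4.87-fold and Top2a, a topoisomerase of dividing cells, 3.17-fold. Of 26 lysosome genes, 24 rose and 1 fell (adjusted p = 8.0e-09, adjusted p = 0.233 with an estimated correlation), and Ctss, a protease gene, reached 5136 ± 386 CPM from 1234 ± 43.4 CPM. All 21 oxidative phosphorylation genes rose, with a median log2 change of 0.67 (adjusted p = 3.7e-06, adjusted p = 0.295 with an estimated correlation). Of 19 glycolysis and hypoxia genes, 15 rose and 3 fell (adjusted p = 0.0065, adjusted p = 0.233 with an estimated correlation). Of 20 type I interferon-stimulated genes, 14 rose and 1 fell, with a median log2 change of 0.51 (adjusted p = 0.00202, adjusted p = 0.233 with an estimated correlation). Usp18, a negative regulator of interferon signalling, rose 4.01-fold.

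The genes of nonclassical monocytes, the patrolling blood monocytes, fell in 11 of 12 cases and rose in 1 (median log2 change -2.08, adjusted p = 8.9e-06, adjusted p = 0.233 with an estimated correlation). Cd300e fell from 93.9 ± 7.13 to 8.46 ± 0.91 CPM and Treml4 from 195 ± 12.1 to 22.8 ± 2.57 CPM. Of 13 classical monocyte genes, 7 rose and 5 fell, which gave no list call (adjusted p = 0.674). Ccr2, a chemokine receptor of recruited monocytes, rose 3.23-fold. Of 23 growth factor and matrix remodelling genes, 13 rose and 7 fell (adjusted p = 0.1), and Mmp14, a membrane metalloprotease gene, rose 9.09-fold. Of 16 genes of IL-4-type alternative activation, 12 rose and 4 fell (adjusted p = 0.0218, adjusted p = 0.233 with an estimated correlation). No call was made for inflammatory cytokines and NF-kB feedback (6 higher and 9 lower of 18, adjusted p = 0.664) or for complement (7 higher and 3 lower of 11, adjusted p = 0.353). Resident interstitial macrophage genes also had no list call (8 higher and 7 lower of 17, adjusted p = 0.938), and there the median change was 0.11 and the mean -0.68. Lists for MHC class II presentation (4 higher and 5 lower of 12, adjusted p = 0.799) and alveolar macrophage identity (6 higher and 9 lower of 17, adjusted p = 0.64) had none either.

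Markers of other cells moved with these groups. Of 11 lung epithelial markers, 10 fell and 1 rose (adjusted p = 2.8e-05, adjusted p = 0.248 with an estimated correlation). The surfactant gene Sftpc fell from 1385 ± 111 to 8.89 ± 1.15 CPM and the club cell gene Scgb1a1 from 3212 ± 882 to 41.8 ± 7.37 CPM. All 10 neutrophil markers fell (adjusted p = 9.2e-06, adjusted p = 0.248 with an estimated correlation), as did all 8 B cell markers (adjusted p = 4.8e-05, adjusted p = 0.259 with an estimated correlation) and all 8 fibroblast markers (adjusted p = 5.4e-04, adjusted p = 0.248 with an estimated correlation). The neutrophil granule gene Ltf fell from 532 ± 30.2 to 30.0 ± 3.55 CPM. All 7 NK cell markers rose (adjusted p = 0.0296, adjusted p = 0.248 with an estimated correlation). Of 13 dissociation stress genes, 7 rose and 5 fell, or 8 and 5 adjusted over the list alone (adjusted p = 0.299), and of 12 mitochondrially encoded transcripts 7 fell (adjusted p = 0.0296, adjusted p = 0.264 with an estimated correlation). Hc, complement component 5, fell from 69.0 ± 5.42 to 0.25 ± 0.08 CPM.

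Of 15645 genes tested, 5567 were higher and 5390 lower after bleomycin, and 1653 and 2410 of these changed at least 2-fold. In the list of lipid uptake, storage and efflux, 12 of 19 genes rose and 4 fell, or 5 fell adjusted over the list alone (adjusted p = 0.0221, adjusted p = 0.292 with an estimated correlation). Of 20 cholesterol biosynthesis genes, 15 rose and 3 fell (adjusted p = 0.00509, adjusted p = 0.233 with an estimated correlation). No list call in this comparison held with an estimated correlation.

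The comparison of EGFP+ with EGFP- IMs at day 7 asks how cells that express the reporter differ from those that do not, in the same gate and treatment. Spp1 was 7.65-fold higher in EGFP+ cells (log2 fold change 2.94 ± 0.19 SE, adjusted p = 6.4e-06, 3 against 3 libraries). Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, was higher at 146 ± 35.5 against 13.3 ± 0.27 CPM, and the elastase gene Mmp12 was 5.57-fold higher at 1397 ± 115 CPM. Lpl (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448) was 3.42-fold higher, at 2024 ± 91.6 against 592 ± 7.39 CPM. Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801) was 3.04-fold higher, at 683 ± 23.3 against 224 ± 11.7 CPM. Fn1 was 2.33-fold higher, at 9533 ± 512 CPM. Itgam did not differ by the test (adjusted p = 0.907). Siglecf was 1.68-fold lower in EGFP+ cells, at 14.6 ± 1.2 against 24.5 ± 0.93 CPM, with no overlap between replicates. It was not past the test (adjusted p = 0.169), in a fit whose spread also comes from the day 14 IMs.

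Of 20 lipid-associated macrophage genes, 18 were higher in EGFP+ cells and none was lower (adjusted p = 4.9e-11, adjusted p = 0.178 with an estimated correlation). The list of lipid uptake, storage and efflux was called with either correlation, with 13 of 18 higher and 1 lower, or 14 higher and 1 lower adjusted over the list alone (adjusted p = 6.2e-06, adjusted p = 0.0369 with an estimated correlation). Its member Fabp5, a fatty acid binding protein gene, was 2.02-fold higher. All 29 cell cycle genes were higher, with a median log2 difference of 1.17 (adjusted p = 8.9e-16, adjusted p = 0.178 with an estimated correlation), and Ccna2 was 2.75-fold higher at 29.3 ± 3.72 CPM. Of 26 lysosome genes, 19 were higher, or 20 higher and 1 lower adjusted over the list alone (adjusted p = 1.8e-08, adjusted p = 0.253 with an estimated correlation). Of 21 oxidative phosphorylation genes, 13 were higher, or 16 adjusted over the list alone (adjusted p = 5.7e-06, adjusted p = 0.331 with an estimated correlation). Of 23 growth factor and matrix remodelling genes, 11 were higher and 3 lower, or 4 lower adjusted over the list alone (adjusted p = 0.0262, adjusted p = 0.253 with an estimated correlation). The platelet-derived growth factor gene Pdgfc was 3.15-fold higher, at 17.7 ± 3.04 CPM.

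Of 16 alveolar macrophage identity genes, 9 were higher in EGFP+ cells, or 10 adjusted over the list alone (adjusted p = 3.7e-05, adjusted p = 0.219 with an estimated correlation). Marco, a scavenger receptor gene of AMs, was 14.8-fold higher at 35.3 ± 5.66 CPM, and the ribonuclease gene Ear1 stood at 2.81 ± 0.70 CPM against 0.079 ± 0.14 CPM. By CPM of the total count, Marco stood at 37.5 ± 6.24 in these cells and at 261 ± 4.62 in PBS AMs, and Ear1 at 2.98 ± 0.74 and 538 ± 30.5.

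Type I interferon-stimulated genes were lower in EGFP+ cells in 17 of 20 cases, or 18 adjusted over the list alone (median log2 difference -1.04, adjusted p = 3.1e-07, adjusted p = 0.346 with an estimated correlation). Oas2, an antiviral enzyme gene, stood at 57.8 ± 10.7 against 152 ± 2.40 CPM. Inflammatory cytokines and NF-kB feedback genes were lower in 11 of 18 cases and higher in 1, or 12 and 1 adjusted over the list alone (adjusted p = 0.00222, adjusted p = 0.346 with an estimated correlation). The chemokine gene Ccl3 was 1.91-fold lower and Nfkbiz, a regulator of NF-kB targets, 1.73-fold lower, while the chemokine gene Cxcl1 was 2.04-fold higher. Of 12 MHC class II presentation genes, 5 were lower (adjusted p = 0.00737, adjusted p = 0.57 with an estimated correlation), among them the costimulator genes Cd40 and Cd86, 2.19-fold and 1.66-fold lower. All 10 neutrophil markers were lower as well (median log2 difference -1.24, adjusted p = 8.9e-04, adjusted p = 0.3 with an estimated correlation). The neutrophil chemokine receptor gene Cxcr2 stood at 121 ± 23.6 against 301 ± 15.7 CPM. Of 8 dendritic cell markers, 6 were lower (adjusted p = 0.0206, adjusted p = 0.295 with an estimated correlation), and of 13 dissociation stress genes, 7 were lower (adjusted p = 0.0206, adjusted p = 0.3 with an estimated correlation).

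Of 14967 genes tested, 2571 were higher and 2635 lower in EGFP+ cells, and 566 and 657 of these differed at least 2-fold. With only the 2 groups compared in the fit, 4064 genes were higher, and without EGFP+ replicate 2 the counts were 1670 higher and 1610 lower.

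**Figure D2:**
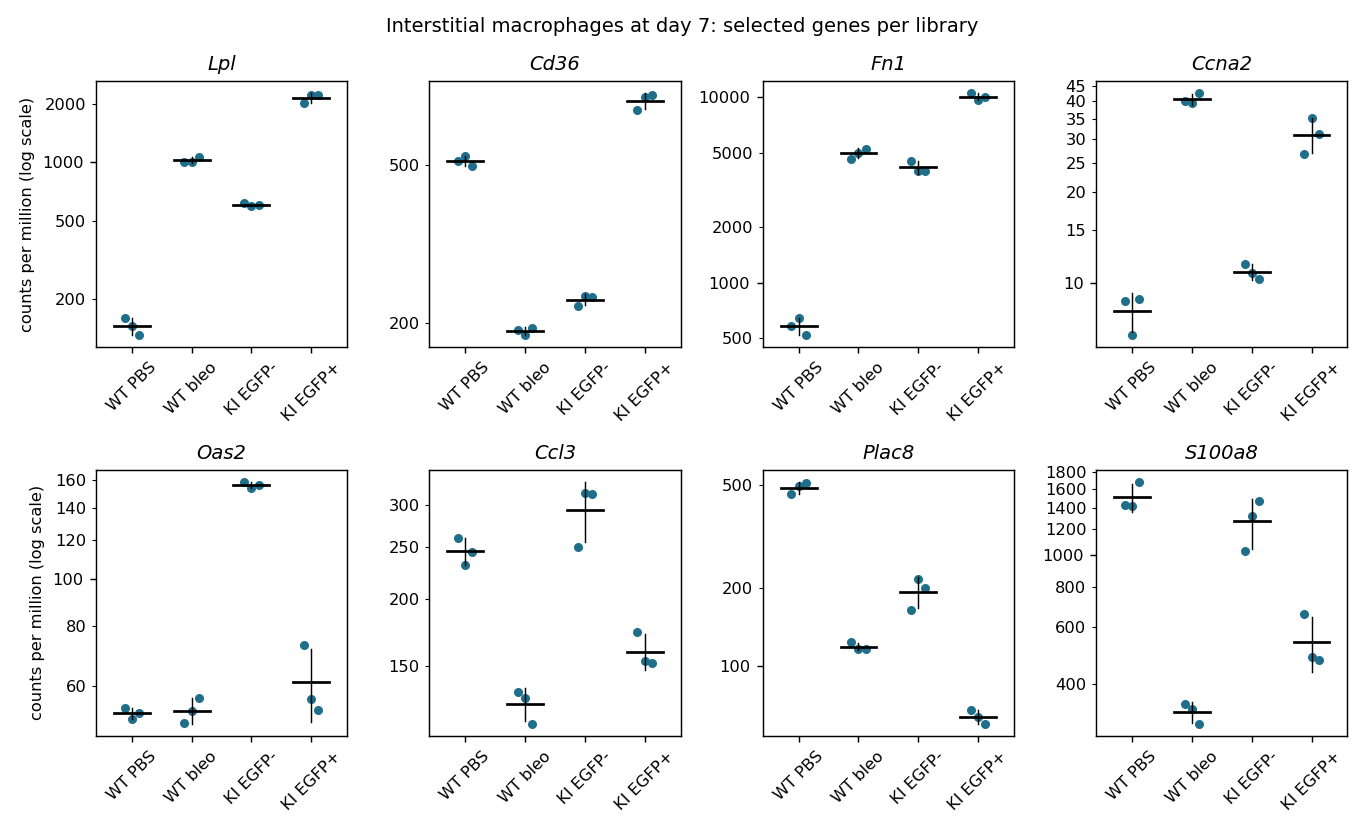
CPM of the total count on log axes for 8 genes in the IM groups of day 7, with points for libraries and bars and lines for the mean and SD of 3 libraries per group (wild-type after PBS, wild-type after bleomycin, reporter EGFP- and EGFP+ after bleomycin). Lpl, Cd36, Fn1 and Ccna2 are higher in EGFP+ than in EGFP- libraries, and Oas2, Ccl3, Plac8 and S100a8, a neutrophil marker, are lower.

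The genes that bleomycin changed in wild-type IMs and those that differed by EGFP overlapped. Over the 14499 genes tested in both, 2154 were higher in both where 967 would be expected from the call counts, and 1846 were lower in both where 825 would be expected. Genes called in opposite directions numbered 269, higher after bleomycin and lower in EGFP+ cells, and 121 the other way, where 987 and 808 would be expected. Pearson's r of the log2 fold changes was 0.492 and Spearman's rho 0.592, across genes, which are not independent replicates. No library is shared by these comparisons. Every neutrophil marker was lower both after bleomycin and in EGFP+ cells. How much of the overlap goes with cells other than macrophages in the gate was not tested. Cd36 is one of the 121, lower after bleomycin and higher in EGFP+ cells.

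The comparison of EGFP+ IMs at day 14 and day 7 follows reporter cells of one gate over time. Spp1 was 1.66-fold higher at day 14 (log2 fold change 0.73 ± 0.18 SE, adjusted p = 0.00487). Itgam was 1.47-fold lower (adjusted p = 0.0413), with overlapping replicates. Its call was not made without the low-count filter, with only the 2 groups compared, or without any one of day 7 replicates 1, 2 and 3 and day 14 replicates 2 and 3. Siglecf did not differ by the test (adjusted p = 0.137), but was called lower with all libraries in one fit and without day 14 replicate 1. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), which encodes a lipid carrier protein, rose 5.19-fold to 23870.0 ± 8816 CPM. The folate receptor gene Folr2, a marker of resident macrophages, rose 11.5-fold to 66.8 ± 20.5 CPM, and the chemokine gene Ccl8 rose from 2.45 ± 0.79 to 59.9 ± 33.9 CPM. Of 16 resident interstitial macrophage genes, 7 rose and 1 fell (adjusted p = 0.0214, adjusted p = 0.383 with an estimated correlation). Of 11 complement genes, 6 rose and 1 fell (adjusted p = 0.0124, adjusted p = 0.383 with an estimated correlation), with C1qa at 2767 ± 630 CPM, 3.86-fold higher.

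Of 20 lipid-associated macrophage genes, 15 rose and none fell (adjusted p = 3.3e-05, adjusted p = 0.383 with an estimated correlation), with the lipid receptor gene Trem2 2.64-fold higher. Of 26 lysosome genes, 24 rose (adjusted p = 2.6e-07, adjusted p = 0.383 with an estimated correlation), and the glucuronidase gene Gusb was 2.03-fold higher. In the list of lipid uptake, storage and efflux, 10 of 18 rose and 1 fell (adjusted p = 0.00249, adjusted p = 0.205 with an estimated correlation). Of 21 cholesterol biosynthesis genes, 11 rose (adjusted p = 0.00249, adjusted p = 0.539 with an estimated correlation), and of 21 oxidative phosphorylation genes 17 rose and 2 fell (adjusted p = 6.9e-05, adjusted p = 0.383 with an estimated correlation).

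Type I interferon-stimulated genes fell in 17 of 20 cases, or 18 adjusted over the list alone (median log2 change -1.69, adjusted p = 6.1e-06, adjusted p = 0.383 with an estimated correlation), with Oas2 5.23-fold lower. Of 18 inflammatory genes, 12 fell and 1 rose (adjusted p = 0.00287, adjusted p = 0.383 with an estimated correlation), and Tnf fell 3.48-fold. Beside them, 5 of 13 dissociation stress genes fell and 1 rose, with no list call (adjusted p = 0.141), and the heat shock gene Hspa1a fell 4.49-fold and Jun, an early response gene, 1.47-fold. Of 29 cell cycle genes, 24 fell (adjusted p = 1.5e-05, adjusted p = 0.383 with an estimated correlation), and the proliferation marker Mki67 fell from 167 ± 12.9 to 50.6 ± 6.47 CPM. Of 13 classical monocyte genes, 6 fell (adjusted p = 0.0251, adjusted p = 0.373 with an estimated correlation), with Ly6c2 10.2-fold lower. Neutrophil markers fell in 10 of 10 cases (adjusted p = 6.2e-06, adjusted p = 0.182 with an estimated correlation), and Cxcr2 fell 44.5-fold. All 8 dendritic cell markers fell (adjusted p = 2.1e-04, adjusted p = 0.0693 with an estimated correlation), as did 10 of 11 epithelial markers (adjusted p = 8.1e-04, adjusted p = 0.372 with an estimated correlation) and 6 of 7 NK cell markers (adjusted p = 0.0171, adjusted p = 0.458 with an estimated correlation). Of 11 mitochondrially encoded transcripts, 10 rose (adjusted p = 1.2e-04, adjusted p = 0.458 with an estimated correlation). None of the 11 counted as an unchanged model. That rule also compares chromosome names, and whether their start or end differs was not checked separately.

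Of 14967 genes tested, 3781 were higher and 4025 lower at day 14, and 758 and 2007 of these changed at least 2-fold. The groups lie in different tables and differ in Xist, a transcript of female cells, at 689 ± 49.7 CPM of the total count at day 7 and 0.0205 ± 0.0355 at day 14. Day 14 replicate 1 stood apart, with Itgam at 336 CPM of the total count beside 184 and 151 in replicates 2 and 3, and Siglecf at 2.43 beside 9.57 and 10.3. All 20 genes that the naming rule took by size of change have gene models that differ between the tables or lie on a sex chromosome, such as Rps10 at 290.3 ± 10.9 CPM at day 7 and 1.16 ± 0.20 CPM at day 14. With autosomal genes of unchanged models, a choice made after the values were seen, 2607 genes were higher and 3118 lower of 11188 tested. This keeps 72.9% of all 7806 calls, of which a share of 0.767 has an unchanged model, sex chromosomes included. Most of the calls not kept are thus of genes left out of that test.

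The comparison of EGFP+ AMs at day 14 after bleomycin with EGFP+ AMs at day 7 after PBS asks how EGFP+ cells of the alveolar gate differed after injury. By CPM of the total count, Spp1 stood at 202 in these PBS AMs, below the 518 of EGFP- IMs at day 7. The EGFP+ label thus does not mark a like level of Spp1 in both groups. Spp1 was 27.0-fold higher after bleomycin (log2 fold change 4.76 ± 0.18 SE, adjusted p = 2.0e-09), and Siglecf was 2.98-fold lower, while Itgam did not differ by the test (adjusted p = 0.635). The complement genes C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187) and C4b rose 49.3-fold and 54.9-fold, C1qb to 572 ± 124 CPM. Msr1, a scavenger receptor gene, rose 32.9-fold to 337 ± 32.5 CPM, and Ldhb, a lactate dehydrogenase gene, 96.1-fold to 75.0 ± 22.9 CPM. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), an inflammatory cytokine gene, rose 7.60-fold to 2634 ± 467 CPM, and Fn1 rose 7.56-fold to 7809 ± 1605 CPM. Arg1, whose gene model differs between the tables, stood at 311 ± 119 against 0.60 ± 0.13 CPM.

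Of 20 alveolar macrophage identity genes, 11 fell and 2 rose (adjusted p = 0.01, adjusted p = 0.308 with an estimated correlation). The keratin gene Krt79 (ENSMUSG00000061397, chromosome 15, 101929332 to 101940324) fell 26.0-fold from 879.5 ± 10.2 CPM, the keratin gene Krt19 fell 15.4-fold, and the lipid droplet gene Cidec fell 14.0-fold. Of 11 complement genes, 7 rose and 1 fell (median log2 change 3.42, adjusted p = 2.8e-04, adjusted p = 0.104 with an estimated correlation). Type I interferon-stimulated genes rose in 17 of 19 cases, or 18 adjusted over the list alone (median 2.05, adjusted p = 7.4e-09, adjusted p = 0.104 with an estimated correlation), with Oasl2 at 21.2 ± 4.32 against 2.17 ± 0.44 CPM. Of 18 inflammatory genes, 10 rose and 3 fell (adjusted p = 0.01, adjusted p = 0.342 with an estimated correlation), and Ptgs2, the inducible cyclooxygenase gene, rose 11.5-fold. Beside them, dissociation stress genes went both ways, 4 higher and 6 lower of 13, with no list call (adjusted p = 0.352), and Hspa1b fell from 66.5 ± 3.07 to 7.52 ± 1.65 CPM. Of 9 neutrophil markers, 7 fell and 1 rose, or 7 and 2 adjusted over the list alone (adjusted p = 0.0104, adjusted p = 0.338 with an estimated correlation), and S100a9 fell from 33.5 ± 11.8 to 0.94 ± 0.48 CPM. All 21 cholesterol biosynthesis genes rose (median 1.36, adjusted p = 1.2e-11, adjusted p = 0.104 with an estimated correlation), with Sqle, squalene epoxidase, 4.16-fold higher.

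Of 23 growth factor and matrix remodelling genes, 17 rose and 2 fell (adjusted p = 1.7e-07, adjusted p = 0.104 with an estimated correlation). The EGF receptor ligand gene Areg rose 5.04-fold and the growth factor gene Igf1 4.01-fold. Of 20 lipid-associated macrophage genes, 14 rose and 4 fell (adjusted p = 6.2e-05, adjusted p = 0.137 with an estimated correlation), with Mmp12 15.7-fold and Trem2 4.32-fold higher. Of 26 lysosome genes, 22 rose and 1 fell (adjusted p = 8.8e-08, adjusted p = 0.104 with an estimated correlation). Of 19 glycolysis and hypoxia genes, 15 rose (adjusted p = 3.5e-05, adjusted p = 0.137 with an estimated correlation), with Slc2a1, a glucose transporter gene, 2.45-fold higher. Beside these, all 8 B cell markers fell (adjusted p = 6.4e-06, adjusted p = 0.0412 with an estimated correlation) and 9 of 10 epithelial markers fell (adjusted p = 1.5e-05, adjusted p = 0.0924 with an estimated correlation). The immunoglobulin gene Igkc fell from 747 ± 47.9 to 37.3 ± 6.80 CPM. Of 12 mitochondrially encoded transcripts, 11 rose, or 12 adjusted over the list alone (adjusted p = 3.3e-05, adjusted p = 0.0412 with an estimated correlation). None of the 12 counted as an unchanged model, by the rule that also compares chromosome names.

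Of 14706 genes tested, 4008 were higher and 4060 lower, and 1026 and 1693 of these changed at least 2-fold. Table, day and treatment all differ between these groups, and Xist stood at 350 ± 30.4 CPM of the total count in PBS AMs and had no count in the day 14 AMs. The Y-linked gene Ddx3y stood at 79.9 ± 0.81 CPM of the total count in the same PBS AMs. Of the 20 genes that the naming rule took by size of change, 13 have changed gene models. With autosomal genes of unchanged models, chosen after the values were seen, 2926 genes were higher and 3008 lower of 10998.

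The comparison of EGFP+ AMs at day 30 after bleomycin with the same PBS AMs covers the late stage. Spp1 was 36.5-fold higher (log2 fold change 5.19 ± 0.19 SE, adjusted p = 1.2e-09), Siglecf 2.85-fold lower and Itgam 3.09-fold higher. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) rose 32.5-fold to 525 ± 5.71 CPM, and Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) rose 7.49-fold to 353 ± 25.9 CPM. Mfge8, which encodes a bridge between macrophages and dying cells, rose 35.1-fold to 1103 ± 37.9 CPM, and Fabp5 rose 5.78-fold. Fabp1, a fatty acid binding protein gene, fell 15.9-fold and Krt79 fell 13.8-fold. Krt79 stood at 63.5 ± 5.79 CPM.

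All 19 measured type I interferon-stimulated genes rose (adjusted p = 1.5e-09, adjusted p = 0.0937 with an estimated correlation), as did all 21 cholesterol biosynthesis genes (adjusted p = 2.7e-11, adjusted p = 0.0937 with an estimated correlation). Of 26 lysosome genes, 25 rose (adjusted p = 3.9e-11, adjusted p = 0.0937 with an estimated correlation), with Psap, a lysosomal sphingolipid activator gene, at 14250.0 ± 391 CPM. Of 20 lipid-associated macrophage genes, 15 rose and 1 fell (adjusted p = 7.3e-08, adjusted p = 0.0937 with an estimated correlation). Of 23 growth factor and matrix remodelling genes, 17 rose and 2 fell (adjusted p = 4.2e-07, adjusted p = 0.0937 with an estimated correlation), with Igf1 5.57-fold higher. Of 11 complement genes, 7 rose and 1 fell (adjusted p = 9.1e-04, adjusted p = 0.0937 with an estimated correlation). Of 16 resident interstitial macrophage genes, 11 rose and 1 fell, or 12 and 2 adjusted over the list alone (adjusted p = 0.00194, adjusted p = 0.238 with an estimated correlation). Of 13 classical monocyte genes, 6 rose, or 7 adjusted over the list alone (adjusted p = 0.0105, adjusted p = 0.142 with an estimated correlation).

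Of 20 alveolar macrophage identity genes, 11 fell and 4 rose (adjusted p = 9.1e-04, adjusted p = 0.166 with an estimated correlation). Of 12 MHC class II presentation genes, 7 fell (adjusted p = 0.0106, adjusted p = 0.314 with an estimated correlation), a call not made with autosomal genes of unchanged models, of which 4 members were measured. Inflammatory genes went both ways, 8 higher and 8 lower of 18, or 9 and 9 adjusted over the list alone (adjusted p = 0.778), with a median log2 change of -0.01 and a mean of 0.22. Nlrp3, an inflammasome gene, fell 2.76-fold and Il6 2.21-fold. The heat shock genes Hspa1a and Hspa1b, which are near copies of each other, stood at 1987 ± 43.1 and 2258 ± 138 CPM against 49.7 ± 1.01 and 66.5 ± 3.07 CPM. Of 13 dissociation stress genes, which include both, 5 rose and 4 fell, or 6 and 4 adjusted over the list alone (adjusted p = 0.155). Beside these, all 7 fibroblast markers rose (adjusted p = 0.00113, adjusted p = 0.323 with an estimated correlation) to levels such as 20.9 ± 1.34 CPM for the collagen gene Col1a1, and all 8 T cell markers rose (adjusted p = 0.00691, adjusted p = 0.323 with an estimated correlation). Of 9 neutrophil markers, 6 rose, or 7 adjusted over the list alone (adjusted p = 0.00729, adjusted p = 0.323 with an estimated correlation), and all 3 measured erythroid markers rose (adjusted p = 0.0335, adjusted p = 0.323 with an estimated correlation).

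Of 14706 genes tested, 3649 were higher and 3401 lower, and 1343 and 985 of these changed at least 2-fold. The limits given for day 14 hold here too, 17 of the 20 genes taken by size of change have changed gene models, and with autosomal genes of unchanged models 2619 genes were higher and 2489 lower. Over 14706 genes, 2349 were higher against PBS on both days where 995 would be expected, and 2299 were lower on both where 939 would be expected. Opposite calls numbered 155 and 235, where 927 and 1007 would be expected. Both comparisons use the same 3 PBS libraries. The covariance of their log2 fold changes was 0.943, across genes, which are not independent replicates. In simulations without an effect that share controls in the same way it was 0.0244, and Pearson's r was 0.458 against 0.640 in the data. The simulations hold no shift between the tables, which would enter both comparisons alike. They bear only on the sharing of controls, and neither they nor the overlaps can tell such a shift from an effect of bleomycin.

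The comparison of day 30 with day 14 in EGFP+ AMs lies within one table. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) fell 5.30-fold by day 30, from 88.1 ± 5.83 to 16.6 ± 1.14 CPM (adjusted p = 4.6e-11). Il1b fell 4.91-fold, Cd14, a receptor for bacterial lipopolysaccharide, 4.82-fold to 519 ± 17.3 CPM, and Areg 5.28-fold. Arg1 fell 5.27-fold, from 311 ± 119 to 59.1 ± 6.45 CPM, and Ccr2 4.33-fold. Trem2 rose 1.74-fold, Mmp12 2.07-fold and Cd36 4.75-fold, to 245 ± 29.2 CPM. Spp1 was 1.35-fold higher at day 30 (log2 fold change 0.43 ± 0.16 SE, adjusted p = 0.0475), which was not past the test in DESeq2, with only the 2 groups compared, or without any one of 5 libraries. Those were day 14 replicates 2 and 3 and each day 30 replicate. Itgam rose 3.38-fold and Siglecf did not differ by the test (adjusted p = 0.562).

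Of 18 inflammatory genes, 12 fell and 6 rose (adjusted p = 0.00678, adjusted p = 0.364 with an estimated correlation). Of 12 MHC class II presentation genes, 8 fell and 1 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.00678, adjusted p = 0.364 with an estimated correlation), with Cd86 2.57-fold lower. Of 11 complement genes, 7 fell and none rose (adjusted p = 0.00678, adjusted p = 0.349 with an estimated correlation), and C4b fell 3.28-fold. Of 19 glycolysis and hypoxia genes, 11 fell and 2 rose, or 11 and 3 adjusted over the list alone (adjusted p = 0.00678, adjusted p = 0.364 with an estimated correlation). Of 16 genes of IL-4-type alternative activation, 7 fell and 2 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.0169, adjusted p = 0.364 with an estimated correlation). Of 20 lipid-associated macrophage genes, 13 rose and 1 fell (adjusted p = 6.2e-04, adjusted p = 0.349 with an estimated correlation), and of 16 resident interstitial macrophage genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 0.00678, adjusted p = 0.364 with an estimated correlation). Alveolar macrophage identity genes had no list call (6 higher and 6 lower of 20, adjusted p = 0.815), while Krt19 rose 2.91-fold and Ear1 2.70-fold, to 158 ± 9.82 CPM.

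Markers of many other cells were higher at day 30. All 8 B cell markers rose (median log2 change 3.46, adjusted p = 2.2e-07, adjusted p = 0.0239 with an estimated correlation), as did all 8 T cell markers (adjusted p = 3.8e-05, adjusted p = 0.141 with an estimated correlation), all 7 fibroblast markers (adjusted p = 4.7e-06, adjusted p = 0.117 with an estimated correlation) and all 3 measured erythroid markers (adjusted p = 0.00193, adjusted p = 0.117 with an estimated correlation). Of 9 neutrophil markers, 8 rose and 1 fell (adjusted p = 3.1e-06, adjusted p = 0.0733 with an estimated correlation), and of 10 epithelial markers 7 rose and 1 fell (adjusted p = 0.00129, adjusted p = 0.122 with an estimated correlation). S100a9 stood at 194 ± 18.7 against 0.94 ± 0.48 CPM and Ighm at 363 ± 43.2 against 11.1 ± 3.74 CPM. Of 5 endothelial markers, 3 rose, or 4 adjusted over the list alone (adjusted p = 0.0265, adjusted p = 0.157 with an estimated correlation). Of 12 mitochondrially encoded transcripts, 10 fell, or 11 adjusted over the list alone (adjusted p = 3.8e-05, adjusted p = 0.0239 with an estimated correlation). Of 13 dissociation stress genes, 5 rose and 6 fell, with no list call (adjusted p = 0.415). Hspa1a and Hspa1b rose 195-fold and 301-fold, whereas Zfp36, which encodes an mRNA decay factor, fell from 736 ± 41.5 to 462 ± 48.5 CPM. Of 14706 genes tested, 2887 were higher and 2753 lower at day 30, and 1354 and 315 of these changed at least 2-fold.

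**Figure D3:**
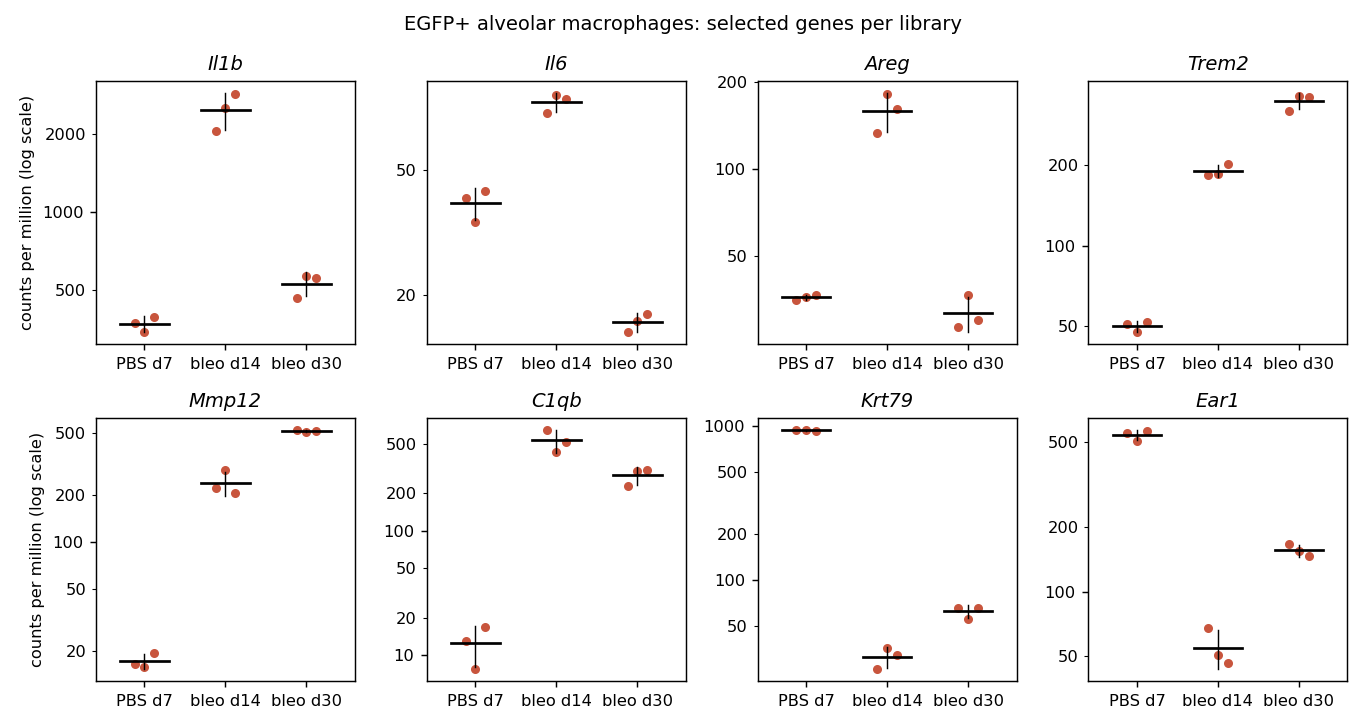
CPM of the total count on log axes for 8 genes in EGFP+ AMs after PBS (day 7) and after bleomycin (days 14 and 30), with points for the 3 libraries of each group and bars and lines for their mean and SD. Il1b, Il6 and Areg are highest at day 14, Trem2 and Mmp12 at day 30, and Krt79 and Ear1 after PBS. The PBS libraries lie in the other table from the later ones, and the gene model of Ear1 differs between the tables.

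The comparison of EGFP+ IMs with EGFP+ AMs at day 14 asks how reporter cells of the gates differ on one day, within one table. Spp1 did not differ by the test (log2 difference 0.40 ± 0.25 SE, adjusted p = 0.306, 6079 ± 1303 against 4622 ± 1361 CPM). With replicate number as a block the log2 difference was 0.41 (adjusted p = 0.117, and 0.0688 to 0.630 over all alternatives), and Spp1 was higher in IMs in 3 of 3 pairs of libraries with one number. Itgam was 32.4-fold higher and Siglecf 14.8-fold lower in IMs. Folr2 (ENSMUSG00000032725, chromosome 7, 101839988 to 101857194) stood at 63.1 ± 19.2 against 0.31 ± 0.30 CPM, and the growth arrest ligand gene Gas6 was 47.4-fold higher in IMs. Apoe was 15.6-fold higher, at 22610.0 ± 8456 CPM. The chemokine genes Ccl8 and Ccl7 reached 56.8 ± 32.5 and 82.1 ± 45.6 CPM in IMs and were under 1 CPM in AMs. Cd36 was 10.2-fold higher and Thbs1, which encodes the matrix protein thrombospondin, 14.4-fold higher in IMs. Krt79 was 211-fold and Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665) 167-fold higher in AMs, and Chil3, a chitinase-like protein gene, 7.65-fold higher in AMs at 14670.0 ± 5225 CPM. Tc2n had no count in IMs and was at least 161-fold higher in AMs.

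Of 19 alveolar macrophage identity genes, 18 were lower in IMs (median log2 difference -3.65, adjusted p = 9.9e-18, adjusted p = 0.0346 with an estimated correlation). Of 15 resident interstitial macrophage genes, 12 were higher in IMs, or 14 adjusted over the list alone (median 3.75, adjusted p = 1.1e-11, adjusted p = 0.102 with an estimated correlation). Of 23 growth factor and matrix remodelling genes, 14 were higher, or 17 higher and 1 lower adjusted over the list alone (adjusted p = 2.0e-07, adjusted p = 0.0731 with an estimated correlation), with Vegfa 4.79-fold higher. Of 29 cell cycle genes, 24 were lower in IMs, or 26 adjusted over the list alone (adjusted p = 2.9e-12, adjusted p = 0.137 with an estimated correlation), with Top2a 2.57-fold lower. Of 21 cholesterol biosynthesis genes, 10 were lower and 1 higher, or 15 and 1 adjusted over the list alone (adjusted p = 2.8e-06, adjusted p = 0.408 with an estimated correlation). Of 20 lipid-associated macrophage genes, 14 were higher and 1 lower (adjusted p = 1.5e-05, adjusted p = 0.348 with an estimated correlation), with Trem2 3.02-fold higher. Of 18 inflammatory genes, 9 were higher, or 10 adjusted over the list alone (adjusted p = 2.6e-04, adjusted p = 0.348 with an estimated correlation), and of 11 complement genes 4 were higher (adjusted p = 0.00913, adjusted p = 0.348 with an estimated correlation). Beside these, 5 of 13 dissociation stress genes were higher in IMs (adjusted p = 0.017, adjusted p = 0.454 with an estimated correlation), with Hspa1a 5.27-fold and Ier3, an early response gene, 2.11-fold higher. Of the neutrophil markers, 4 of 7 were higher in IMs (adjusted p = 0.0234, adjusted p = 0.454 with an estimated correlation), with S100a9 at 34.8 ± 20.1 against 0.85 ± 0.43 CPM. Of 8 B cell markers, 3 were higher, or 5 adjusted over the list alone (adjusted p = 0.00169, adjusted p = 0.454 with an estimated correlation).

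Of 13793 genes tested, 1469 were higher and 1394 lower in IMs, and 842 and 659 of these differed at least 2-fold. With all libraries in one fit the counts were 2937 and 2969, and the count of lower genes was 907 without IM replicate 2, 875 without AM replicate 2 and 911 without AM replicate 3. With replicate number as a block, which the pairing of residuals by number bears on here, 1862 genes were higher and 1823 lower.

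**Figure D4:**
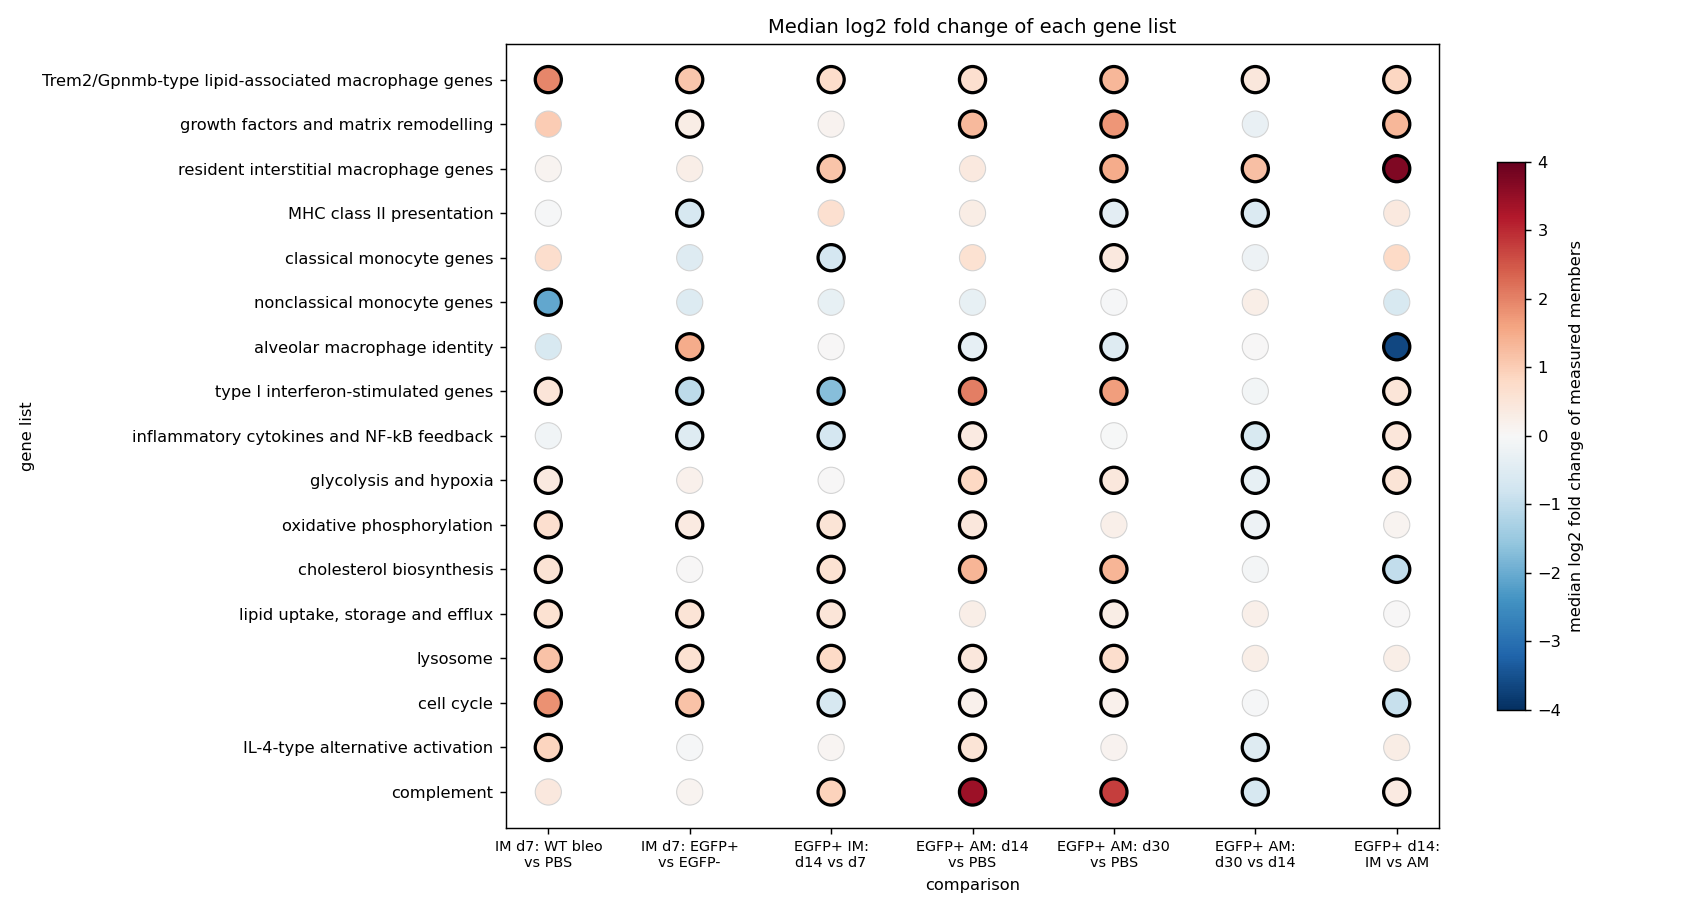
Median log2 fold change (colour, from -4 to 4) of the measured members of the 17 pathway lists (vertical axis) in the 7 comparisons (horizontal axis), with black rings where camera at a correlation of 0.01 gave an adjusted p under 0.05. The lipid-associated list is positive and ringed in all 7 comparisons, though none of these calls held with an estimated correlation. Alveolar macrophage identity is lowest, at -3.65, in IMs against AMs at day 14.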

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

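The tests on genes far lower in one table and on Xist with Y-linked transcripts were chosen only after the result was seen. So were the values with unchanged models.

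In EGFP+ AMs, 390 genes were called against PBS in opposite directions at day 14 and day 30 and were also called between these days. Of these, 155 were higher at day 14 and lower at day 30, and 235 were lower at day 14 and higher at day 30. The opposite calls were as many before the test between the days, which removed none and so adds no separate evidence. Both directions rest on the same 3 PBS libraries, which lie in the other table. Il6 stood at 36.9 CPM after PBS, 88.1 CPM at day 14 and 16.6 CPM at day 30, and Nlrp3 at 446, 531 and 162 CPM. The heat shock gene Hspa1b stood at 66.5, 7.52 and 2258 CPM, and the neutrophil marker S100a9 at 33.5, 0.94 and 194 CPM. Members of the fixed lists among the 390 include 7 inflammatory genes, 5 dissociation stress genes, 4 neutrophil markers and 3 MHC class II genes.

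The day 14 and day 7 EGFP+ IMs lie in different tables, and 7806 genes were called between them. Differing coordinates cannot be the direct source of every call, since a share of 0.83 of the called genes has the same coordinates in both tables. That share was 0.84 among all tested genes, so the bound set for it could hardly have failed. X- and Y-linked genes make up a share of 0.0292 of the calls, with an odds ratio of 0.958 against other genes. That share was bound to be small too, and an effect of sex on autosomal genes was not tested. A shift between the tables common to both gates may account for part, as the log2 fold changes went with those of AMs at day 14 against PBS at r = 0.592 across genes, which are not independent replicates, and at 0.495 with unchanged models. A shift that also acts on day 30 cannot be told apart from a change with time, since the covariance with the day 30 comparison was 0.517 of that with day 14, and 0.268 with unchanged models, both between the bounds set for either reading. A set of 18 genes had at least 5 CPM in every library of one table and far less in the other. Their highest level in the low table was under 0.05 of their lowest in the high one, which still let Myl12b reach 8.86 CPM. The share with unchanged models was 0, against 0.782 of the other genes, so the gene models may be their source. A change with day stays open for the other called genes. Every measured neutrophil marker fell between these days too. Among autosomal genes with unchanged models, the largest falls by the naming rule were of Chil1, Il1f9, Slfn4 and the neutrophil marker Cxcr2. Cxcr2 fell from 121 ± 23.6 to 2.72 ± 0.31 CPM. How many of the calls go with other cells in the gate was not tested.

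Of the inflammatory list, 11 members were called lower in EGFP+ than in EGFP- IMs at day 7, while Cxcl1 was 2.04-fold higher. The list call by camera was lost with an estimated correlation. More neutrophils in the EGFP- gate may account for part of these lower levels, but the test cannot decide this. The 11 members called lower had a median log2 difference of -0.74, less than the -1.24 of the neutrophil markers. A change within the macrophages could give the same order. The 8 markers at 10 CPM or more ranged from -1.32 to -0.94, and the labels name no marker beyond CD11b and SiglecF that would remove neutrophils, while 1 of all 10 markers (Mmp8) is also in the growth factor and matrix list. By CPM of the total count, S100a8 stood at 1271 in EGFP- and 540.4 in EGFP+ cells, and Csf3r at 1257 and 519.6. A difference between the macrophages themselves stays open, untested.

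The PBS AM libraries held Xist together with Y-linked transcripts in each of the 3 libraries, so that 1 mislabelled library would not give this. Xist stood at 0.434 to 0.515 of its mean in the day 7 reporter IMs, and 4 Y-linked genes at 0.535 to 0.852 of their means in the later AMs. Cells of male and female mice in one library may account for this, but the bound for that test was set after these levels were seen, so it gives no support and the explanation stays open. The labels name no sex, and no biological explanation was tested.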

How the results depend on the processing

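The values with the same coordinates and with unchanged models were chosen only after the result was seen. No called gene reversed, nor did a called list where its direction was recomputed. Direction was not recomputed with an estimated correlation or in fry's mixed test, and counts were judged by size only. Of 212 recomputed counts, 186 stayed within 1.5 times the reported count. A minimum log2 fold change of 1 left 1653 higher and 2410 lower in wild-type IMs, 566 and 657 in EGFP+ against EGFP- IMs, 758 and 2007 in IMs at day 14 against day 7, 1026 and 1693 in AMs at day 14, 1343 and 985 at day 30, 1354 and 315 between these days, and 842 and 659 in IMs against AMs, which follows from the stricter criterion. The overlaps became 321 and 307 for the day 7 IMs and 676 and 682 for the AMs. With only the groups compared, 4064 genes were higher in EGFP+ IMs, and with all libraries in one fit 2937 were higher and 2969 lower in IMs against AMs, and the cause was not tested. The first of these fits leaves out the day 14 IMs, whose replicates were less alike (Pearson's r of log2 CPM 0.969 to 0.987). Replicates of the day 7 reporter IMs gave 0.992 to 0.994. Leaving out 1 library gave 1670 to 2107 higher and 1610 to 2114 lower in EGFP+ IMs, both lowest without EGFP+ replicate 2, and 875 to 1548 lower in IMs against AMs, lowest without AM replicate 2. These have fewer libraries by construction. With replicate number as a block, IMs against AMs gave 1862 higher and 1823 lower, and there residuals of libraries with one number were closest in 6 of 6 cases (r of 0.148 to 0.246 across genes, which are not independent replicates). Of 646 list settings, 77 lost a call, 72 of these with an estimated correlation, and 58 gained one, 42 with fry's mixed test and 12 with its directional test. Of 6595 gene settings, 61 lost a call and 72 gained one, and of 5496 with 1 library left out, 193 and 43.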

Other observations

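No test in this part was chosen after the result was seen.

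Some gene groups have no place above. Among the fixed lists, 3 eosinophil markers were measured in wild-type IMs, of which 1 rose and 2 fell after bleomycin (median log2 change -1.02, mean 0.42, adjusted p = 0.642). The 4 sex-linked transcripts measured there gave 0 higher and 2 lower (adjusted p = 0.228), and among the 5 measured in EGFP+ against EGFP- IMs none was called (adjusted p = 0.367). T cell markers had no list call in EGFP+ against EGFP- IMs (0 of 8 called, adjusted p = 0.367).

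In EGFP+ IMs the complement gene C1qc, which encodes a chain of C1q, was 2.08-fold higher than in EGFP- IMs at day 7, whereas C4b was 2.37-fold lower. The chemokine genes Ccl17 and Ccl22, which draw T cells, were 1.76-fold and 2.07-fold lower. Mrc1, the mannose receptor gene, stood at 1815 ± 1033 CPM in EGFP+ IMs at day 14 and 378 ± 39.7 CPM at day 7. In AMs at day 30 the growth arrest ligand gene Gas6 was 8.56-fold and the matrix gene Sparc 5.37-fold higher than at day 14, while the transcription factor gene Klf4 was lower, at 246 ± 16.8 against 516 ± 70.2 CPM. Every measured fibroblast marker and Itgam rose in the same comparison, and a source of Gas6 and Sparc in other cells of the gate was not tested.

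The 6 libraries of each comparison make 10 splits into 3 and 3, which are too few for a share under 0.05. In each of the 7 comparisons 1 of the 10 splits, the real one, gave as many called genes. The real values were 10957 genes in wild-type IMs, 5206 in EGFP+ against EGFP- IMs, 7806 in IMs by day, 8068 and 7050 in AMs at day 14 and day 30 against PBS, 5640 between these days, and 2863 in IMs against AMs. The highest of the other splits was 0 in each. Those splits mix libraries of both groups, so the difference between groups enters their spread. Low counts were thus bound to follow, whatever the source of that difference.

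Y-linked Ddx3y stood at 0.205 ± 0.083 CPM of the total count in EGFP- IMs at day 7. In EGFP+ IMs it stood at 9.96 CPM in replicate 2 and at 0.873 and 0.620 CPM in replicates 1 and 3, and the Y-linked genes Eif2s3y, Kdm5d and Uty were also highest in replicate 2, at 3.23, 1.12 and 0.858 CPM.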
